A study of Mus musculus with 2 samples.

How the data were processed

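Chromatin carrying acetylated lysine 27 of histone H3 (H3K27ac), a mark of active promoters and enhancers, was immunoprecipitated and sequenced from mouse midbrain at embryonic day 16.5. The series held 2 biological replicates of this tissue, each made from pooled embryos of both sexes. Replicate 2 pooled 37 embryos, per the labels, and the labels gave no number for replicate 1. There was no second tissue, stage or treatment, so no comparison between groups was possible.

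The authors deposited 4 peak lists on the mm10 assembly. Per the deposited description files, peaks were called for replicate 1 alone, for replicate 2 alone and on the alignments of both replicates together (the pooled list), in each case with a control alignment. The last list held replicated peaks derived from the other 3. All of its peaks were peaks of the pooled list, with the same values, so it added no measurement of its own. The aligner, the peak caller, their versions and the rule for keeping a peak as replicated are not given in the sources used here. Each peak had a signal value, given by the authors relative to the control, with a normalization that is not given in the sources used here. It also had a −log10 p-value, which the authors deposited beside the signal and which was never below 2.00 in any list. The deposited offset of the summit from the start of the peak was used to place motif windows. Signal values belong to the authors' peak calls and were used here to describe, rank or filter peaks within a list. Read depth is unknown, because the lists hold no read counts, so no interval based on depth was computed. A peak absent from a list was not called there at the authors' threshold, which does not show that acetylation was absent.

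Peaks on chromosomes 1 to 19, X and Y were analysed. All peak ends lay within the chromosome lengths of the reference, GRCm38.p6, which is the same assembly as mm10. Genes and transcription start sites (TSSs) came from the GENCODE vM21 basic annotation, in which 21851 protein-coding genes with 41438 distinct protein-coding TSSs were tested. A promoter peak overlapped the window from 1 kb before to 1 kb after a protein-coding TSS by at least 1 bp, and every other peak was called distal. Overlap between lists also meant at least 1 bp. Observed overlaps were set beside 100 seeded random placements of the peaks on their own chromosomes outside assembly gaps.

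The 18 gene lists, the motifs and the rule for naming genes were fixed before the data were examined. The lists covered pan-neuronal, midbrain dopaminergic, midbrain transcription factor, GABAergic and glutamatergic transmission, radial glia and progenitor, cell cycle and oligodendrocyte precursor genes, which the tissue holds. Mature oligodendrocyte, astrocyte, microglia, endothelial and pericyte, and erythroid genes stood for other cell types. Serotonergic, forebrain transcription factor and Hox genes stood for neighbouring regions, liver and muscle and heart genes for unrelated tissues, and housekeeping genes for a positive control. The share of members with a replicated promoter peak was compared with all other protein-coding genes by a two-sided Fisher's exact test. Distal peaks within 100 kb of the gene's 5′ end were averaged over each list and ranked among 10000 random lists of the same size, matched on the number of protein-coding genes within 100 kb. Benjamini-Hochberg adjustment ran over the 18 lists in each family, with a threshold of 0.05. These tests compare genes within these libraries. Genes and peaks are not independent replicates, and with n = 2 no test across samples was made.

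Distal peaks within 10 kb of each other were stitched into domains, which were ranked by the bp that peaks covered. The density of 14 fixed motifs in 500 bp around distal summits was divided by the density in 500 bp windows 5 kb to either side that overlapped no peak of any list and no promoter window. The same ratio was computed for up to 100 letter permutations of each motif with the same CpG content, and its standard error (SE) came from leaving out each chromosome in turn. A motif was called when fewer than 5% of its permutations reached its ratio. Unlike the list tests, these calls were not adjusted over the 14 motifs. Promoters were split at a CpG observed/expected ratio of 0.6 in 1 kb around the 5′ end of the gene record, and the peak was sought within 1 kb of that same end, so counts of genes in that comparison differ slightly from those over all TSSs.

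The rule for genes named in the text took 10 landmark genes, up to 3 members per list with the highest replicated promoter signal, up to 3 per list with no promoter peak in any of the 4 lists, the 10 largest domains that ranked in the top 100 of each replicate, and the 10 widest replicated promoter peaks. Genes outside the rule are named as such.

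Alternatives covered the overlap rule, a stricter signal threshold, the promoter and distal windows, the TSS set, the background genes, the matching of random lists, the stitching distance, the motif windows and flanks, the CpG threshold, and each replicate's own list in place of the replicated list. The last of these left out the other replicate. A further 4 alternatives were chosen after seeing the data: the 5′ end of the gene record as the only TSS, genes with a second protein-coding 5′ end within 2 kb left out, comparison with genes of the same promoter CpG class, and 1 list member per 200 kb locus. The CpG classes were those with an observed/expected ratio of at least 0.6 or below, and the exact test added the hypergeometric counts of both. Their effects are given in the closing section.

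Computation used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, pysam 0.24.0, samtools 1.23.1 and Matplotlib 3.10.9. The functions were tested on simulated data with fixed seeds. For the promoter test on 21851 simulated genes, altered lists of 20 genes were set to a share of 95% or 10%. Of these altered lists 98.6% were called, and of unaltered lists 1.58%. For the distal test, 93.8% of lists of 20 genes given 3 times the mean and 1.61% of unaltered lists were called. Simulated genes were independent. These rates do not carry over to smaller lists, smaller effects or genes in clusters, so a list that failed is not shown to be like other genes. With classes of unlike share, the exact test within classes called 0.111% of unaltered lists.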

Results

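H3K27ac was profiled in mouse midbrain at embryonic day 16.5, when most midbrain neurons have been born and glia are forming, with n = 2 biological replicates of pooled embryos. The deposited lists held 91720 peaks for replicate 1, 86333 for replicate 2, 71178 for the pooled data and 55620 that the authors kept as replicated. Peaks on the main chromosomes covered 47.4 Mb in replicate 1, 46.9 Mb in replicate 2 and 42.3 Mb in the replicated list, which is 1.55% of the genome. The median peak was 295 bp wide in replicate 1, 304 bp in replicate 2 and 476 bp in the replicated list. Read depth was unknown. The data describe which promoters, distal regions and gene groups carried the mark in this tissue, with the spread between replicates as the error.

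The replicates shared their strong peaks and differed in the weak ones. Of the peaks of replicate 1, 60.6% overlapped a peak of replicate 2. In the other direction, 63.3% of replicate 2 peaks overlapped a peak of replicate 1. The mean was 61.9%, with an SD of 1.86 between these directions. Both directions come from a single comparison of 2 lists, so this SD is not an error between replicates. Random placement gave 3.36% and 3.57%. Among the 10% of peaks with the lowest signal, 38.1% were shared in replicate 1 and 36.7% in replicate 2, while among the 10% with the highest signal 100% were shared in both. With a reciprocal overlap of 50% in place of 1 bp the mean was 39.7%. Across the 48682 replicated peaks with a partner in both lists, the Spearman correlation of the signal values was 0.760, with 0.896 for promoter and 0.586 for distal peaks. These correlations are across peaks, which are not independent. The SD of the log2 ratio of replicate 2 to replicate 1 was 0.476 for promoter and 0.474 for distal peaks. The lower distal correlation thus does not show a wider spread between replicates at distal peaks. The Jaccard index of covered bases was 0.533.

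**Figure D1:**
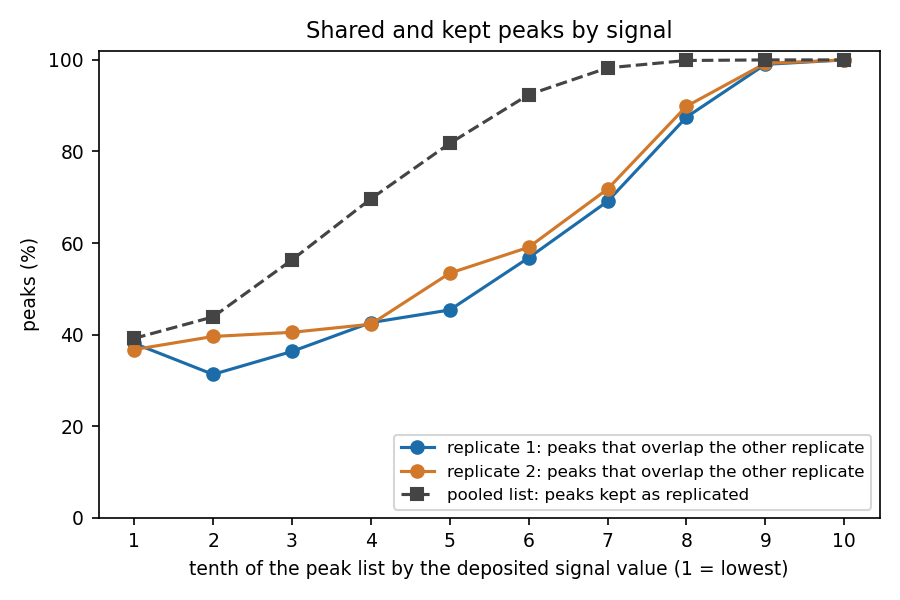
Percentage of peaks (vertical axis) that overlapped the other replicate, for replicate 1 and replicate 2, and of pooled peaks kept as replicated, in 10 equal bins of each list by signal value (horizontal axis, 1 lowest). Sharing was 38.1% and 36.7% in the lowest bin of the replicate lists and 100% in the top bin of both.

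The authors' replication filter kept 55611 of 71169 pooled peaks on the main chromosomes, or 78.1% (95% Wilson interval 77.8 to 78.4, which covers counting error over peaks only). Kept peaks had a median signal of 4.21 and 26.9% lay at promoters. Peaks not kept had a median signal of 2.93 and 7.73% lay at promoters. All 48170 pooled peaks that overlapped a peak of each replicate by at least 50% of either peak were kept. A further 7441 peaks were kept without meeting that overlap, and 6929 kept peaks did not overlap a peak of both replicates even by 1 bp. "Replicated" in this list therefore did not always mean a peak in each replicate's own list.

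Promoters took a small part of the peaks and a larger part of the strong signal. In the replicated list 14957 of 55611 peaks, 26.9%, were at promoters of protein-coding genes, against 2.95% of randomly placed peaks. The replicates' own lists gave 19.4% and 20.3%, a mean of 19.8% ± 0.628 (SD, n = 2). The pooled list gave 22.7%, from which the filter removed mostly distal peaks of low signal. Promoter peaks had a median width of 914 bp and a median signal of 9.71, against 401 bp and 3.85 for distal peaks, and held 41.4% of covered bases. Among peaks above the median signal of the list the promoter share was 44.6%. Of the summits of distal peaks, 55.5% lay in introns, 40.8% outside protein-coding genes and 3.73% in exons, while introns made up 36.5%, regions outside genes 60.7% and exons 2.79% of the genome.

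A replicated promoter peak was present at 11903 of 21851 protein-coding genes, or 54.5%. The landmark genes of the midbrain spanned a wide range. Slc17a6, the vesicular glutamate transporter VGLUT2, had a promoter signal of 36.7 (chromosome 7, 51621255 to 51623171, mm10), and Gad2, which makes GABA, had 22.9 over a peak of 7425 bp (chromosome 2, 22619266 to 22626690). The midbrain and hindbrain patterning genes En2 and En1 had 17.5 and 13.2, and Otx2, a fore- and midbrain determinant, had 14.4 over 6367 bp on chromosome 14 (48664535 to 48670901). Gata3, a factor of midbrain GABAergic neurons, had 9.89, and Foxg1, a telencephalic factor, had 5.64. Promoter peaks were weak or absent at 3 landmark genes of dopaminergic neurons. Nr4a2 had a signal of 4.92 over 524 bp, and Th, the rate-limiting enzyme of dopamine synthesis, had 3.26 over 270 bp in the replicated list but no promoter peak in replicate 2. Pitx3, which dopaminergic neurons need for their survival, had no promoter peak in any of the 4 lists.

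Lists of neuronal, progenitor and housekeeping genes had promoter peaks more often than other genes. All 20 pan-neuronal genes had a replicated promoter peak (adjusted exact p = 3.99e-05, Fisher's test over 18 lists), led by the transcription factor Myt1l at 48.3, the microtubule protein gene Mapt at 46.0 and the adhesion molecule gene Ncam1 at 42.6. Of 20 radial glia and progenitor genes, 19 had a peak (adjusted exact p = 4.91e-04), led by the RNA-binding protein gene Msi1 at 32.3, the Notch ligand gene Dll1 at 29.0 and the Notch target Hes5 at 18.4. Of 16 GABAergic and glutamatergic transmission genes, 15 had a peak (adjusted exact p = 0.00389), among them the GABA-B receptor subunit gene Gabbr1 at 33.5 and the AMPA receptor subunit gene Gria2 at 27.7. The exception was Slc17a7, the VGLUT1 transporter of cortical neurons, and within 2 kb of a TSS all 16 had a peak. Of 26 midbrain transcription factor genes, 22 had a peak (adjusted exact p = 0.00473), led by Meis1 at 26.0, Zic1 at 20.0 and Lhx5 at 16.1, while Helt and Tal2 had none in any list. This call was lost against genes of the same promoter CpG class, which gave 82.8% beside the 84.6% of the list (adjusted exact p = 1, range 2.72e-04 to 1 over 11 alternatives), so the share of this list was that of CpG-rich promoters in general. The other 4 lists passed against genes of their CpG class too. All 20 housekeeping genes had a peak (adjusted exact p = 3.99e-05), with Actb at 75.1, Eef1a1 at 49.4 and Ywhaz at 49.2.

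Hox, liver, muscle and heart, erythroid, microglia and serotonergic genes had promoter peaks less often. None of the 39 Hox genes, which pattern the hindbrain and spinal cord, had a promoter peak in any list (adjusted exact p = 8.13e-13). These genes lie in 4 clusters, and the test counts them as independent, so this p overstates the evidence. No alternative with 1 member per 200 kb was run for the promoter test. None of the 16 liver genes, Alb and Afp among them, had a peak within 1 kb of a protein-coding TSS (adjusted exact p = 3.05e-05). Within 2 kb 2 of 16 did, Apoa1 and Apoa2, named after their values were seen. Of 16 muscle and heart genes, 2 had a peak (adjusted exact p = 0.00213). These were the cardiac myosin gene Myh7 at 19.0 and the muscle myosin light chain gene Mylpf at 12.1, whose promoter lies within 2 kb of the 5′ end of another gene. Of 12 erythroid genes the transferrin receptor gene Tfrc was the only member with a peak, at 19.1 (adjusted exact p = 0.00426). The 4 globin genes of that list have near-identical copies, so their lack of peaks is uncertain. Of 14 microglia genes, 2 had a peak (adjusted exact p = 0.00473), Hexb at 4.20 and C1qb at 2.80, and Aif1, C1qa and C1qc had none. Most erythroid and microglia promoters were poor in CpG, and against genes of the same CpG class neither list passed. Their CpG classes gave 31.5% beside the 8.33% of erythroid genes (adjusted exact p = 0.150, range 0.00120 to 0.150 over 11 alternatives) and 30.7% beside the 14.3% of microglia genes (adjusted exact p = 0.283, range 2.05e-04 to 0.283). None of the 6 serotonergic genes had a replicated promoter peak (adjusted exact p = 0.0146). With replicate 1's list alone, which leaves out replicate 2, the serotonergic list did not pass (adjusted exact p = 0.139, range 0.00277 to 0.139 over 11 alternatives), because Fev, named here after its values were seen, had a peak in that list.

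The other 7 lists did not pass the test. Of 17 dopaminergic genes, 13 had a promoter peak (adjusted exact p = 0.121), with En2, Otx2 and En1 the highest and Aldh1a1, Pitx3 and Slc6a3 without a peak in any list. Without genes that have a second 5′ end within 2 kb, that list passed as higher (adjusted exact p = 0.0432, range 0.0432 to 0.861 over 11 alternatives), and so did the oligodendrocyte precursor list (adjusted exact p = 0.0367, range 0.0367 to 1). Of 20 cell cycle genes, 14 had one (adjusted exact p = 0.221), with Birc5 at 32.3, Kif11 at 21.0 and Cdc20 at 12.0. Of 10 oligodendrocyte precursor genes, 8 had one (adjusted exact p = 0.159), with Lhfpl3 at 7.64, Olig2 at 6.05 and Nkx2-2, which is also in the midbrain transcription factor list, at 5.11. Of 10 mature oligodendrocyte genes, 2 had one (adjusted exact p = 0.0766), the myelin genes Cnp at 5.99 and Mbp at 3.73, and Mbp had none in replicate 1. That list passed as lower in 6 of 11 alternatives (range of the adjusted exact p 0.0110 to 0.577), with 0.0388 without replicate 1 and 0.0110 without replicate 2. Of 12 astrocyte genes, 7 had one (adjusted exact p = 1), led by the transcription factor gene Nfib at 27.5, the glutamate transporter gene Slc1a2 at 18.4 and the transcription factor gene Nfia at 12.3, which neural progenitors also express, while Gfap had none in any list. Of 15 endothelial and pericyte genes, 7 had one (adjusted exact p = 0.645), with Egfl7 at 4.73 and Flt1 at 4.38, and the list passed as lower only among peaks above the median signal (adjusted exact p = 0.00657, range 0.00657 to 0.846 over 11 alternatives). Of 18 forebrain transcription factor genes, 12 had one (adjusted exact p = 0.394), with Lhx2 at 28.7, Six3 at 10.7 and Emx2 at 7.92, and Emx1, Eomes and Gsx2 had none in any list.

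**Figure D2:**
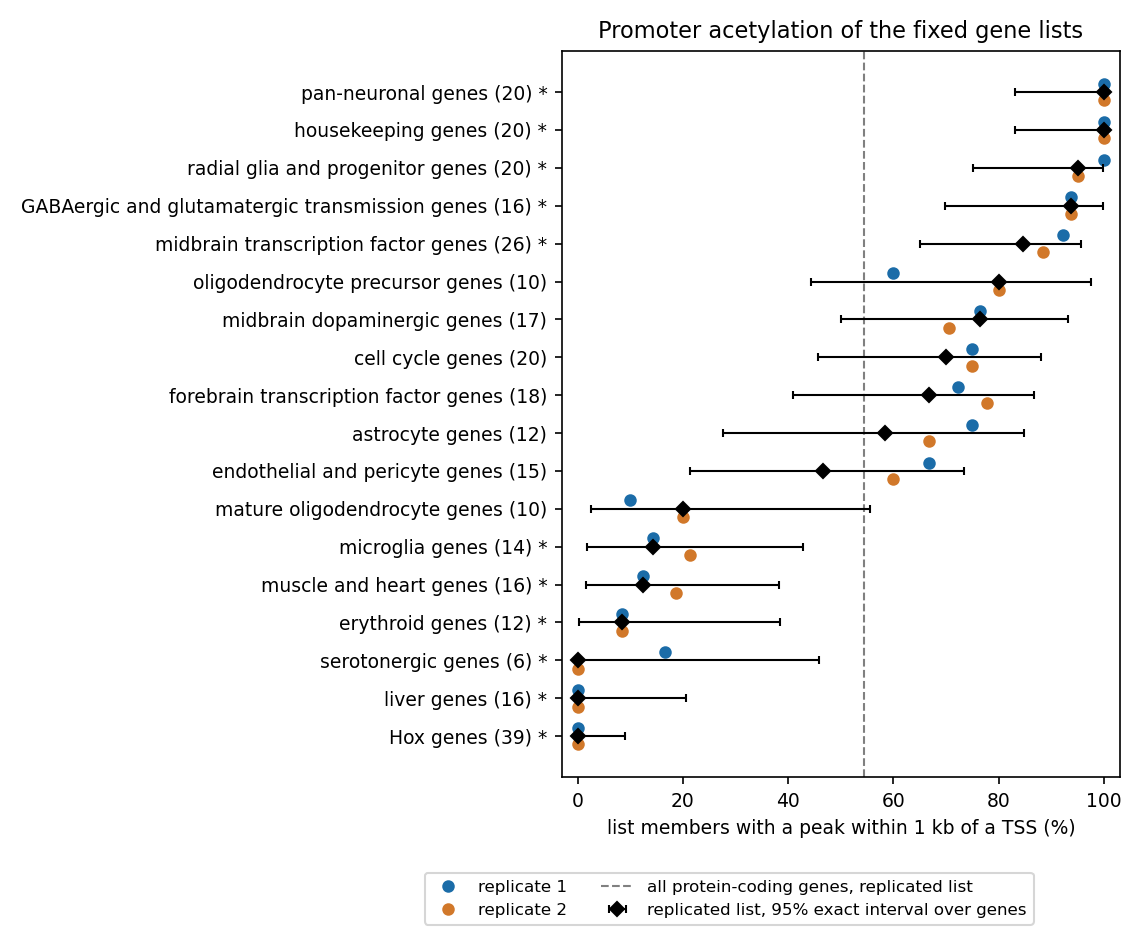
Percentage of members of each fixed gene list (number of members in parentheses) with a peak within 1 kb of a TSS, in the replicated list (diamonds, bars are 95% exact binomial intervals over genes) and in each replicate's list (circles). Asterisks mark the 11 lists past an adjusted p of 0.05, of which 5 lie above and 6 below the dashed line at 54.5% of all protein-coding genes.

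Promoters rich in CpG dinucleotides carried the mark far more often than others. A replicated peak was present at 87.5% of 10039 promoters with a CpG observed/expected ratio of at least 0.6 and at 21.6% of 11812 promoters below it, an odds ratio of 25.5 (95% interval 23.7 to 27.4, Fisher's exact test across genes). The replicates' own lists gave odds ratios of 25.8 for replicate 2 and 25.2 for replicate 1. The Hox genes went against this trend, since 25 of 39 had a CpG-rich promoter and 0 of these had a peak. Of the midbrain transcription factor genes 24 of 26 had a CpG-rich promoter, of which 21 had a peak, a share of CpG-rich promoters like that of all genes. Of the microglia genes 1 of 14, of the erythroid genes 1 of 12 and of the liver genes 1 of 16 had a CpG-rich promoter, each with a peak. The liver gene, Apoh, named here after its values were seen, had it at the 5′ end of its gene record and not at a protein-coding TSS.

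Midbrain transcription factor genes and progenitor genes had more distal peaks nearby than random lists. The former had a mean of 9.96 within 100 kb, against 3.65 in matched random lists (adjusted permutation p = 0.00180, from a p of 2.000e-04, the smallest that the random lists can give). Radial glia and progenitor genes had 8.15 against 3.65 (adjusted permutation p = 0.0204) and pan-neuronal genes 7.50 against 3.61 (adjusted permutation p = 0.0414). Counts differed widely within lists, with 20 at Zic1, 16 at Meis1, 10 at Lhx5 and 2 each at Helt and Tal2. Hox genes had 0.641 against 3.59 (adjusted permutation p = 0.00180), but their members share 4 clusters, and with 1 member per 200 kb, which left 4 members with a mean of 1.00 against 3.56, the list did not pass (adjusted permutation p = 0.308, range 0.00180 to 0.308 over 9 alternatives), nor did it with peaks given to the nearest TSS (0.143), where its ratio to random lists was 0.213 in place of 0.179. The pan-neuronal call, at a ratio to random lists of 2.08, was also lost with 1 member per 200 kb (adjusted permutation p = 0.0927), without replicate 1 (0.0660), above the median signal (0.0936) and with random lists matched also on a promoter peak (0.115), the range over 9 alternatives being 0.00720 to 0.115. The ratios in these 4 were 1.97, 1.81, 2.04 and 1.60. The radial glia call was lost with that matching (adjusted permutation p = 0.0742, ratio 1.78) and with the nearest TSS (0.0504), where the list's ratio to random lists was 2.51 in place of 2.23, with a range of 0.00240 to 0.0742. The midbrain transcription factor list passed in all 9 alternatives.

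The other 14 lists did not pass, though most also lay above their random lists. The ratio to random lists was 2.09 for oligodendrocyte precursor, 2.01 for forebrain transcription factor, 1.99 for microglia and 1.66 for muscle and heart genes. For liver, mature oligodendrocyte and serotonergic genes it was below 1, at 0.743, 0.762 and 0.661. With 2.08 for the pan-neuronal list, an excess was not particular to the lists that passed. The means were 7.50 for oligodendrocyte precursor (adjusted permutation p = 0.110), 6.94 for forebrain transcription factor (0.0670), 6.86 for microglia (0.0689), 6.65 for dopaminergic (0.0823), 6.58 for astrocyte (0.132) and 6.45 for cell cycle genes (0.0689). They were 6.25 for GABAergic and glutamatergic transmission (adjusted permutation p = 0.166), 5.85 for housekeeping (0.110), 5.69 for muscle and heart (0.132), 4.60 for endothelial and pericyte (0.448) and 4.42 for erythroid genes (0.635). Liver genes had 2.63 (adjusted permutation p = 0.616), mature oligodendrocyte genes 2.60 (0.688) and serotonergic genes 2.33 (0.688, random lists). The microglia list passed without replicate 1 (adjusted permutation p = 0.0288) and with random lists matched also on a promoter peak (0.00840), with a range of 0.00840 to 0.479 over 9 alternatives. The number of lists that passed, 4, was 10 within 50 kb, 2 with peaks given to the nearest TSS and 2 with 1 member per 200 kb.

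**Figure D3:**
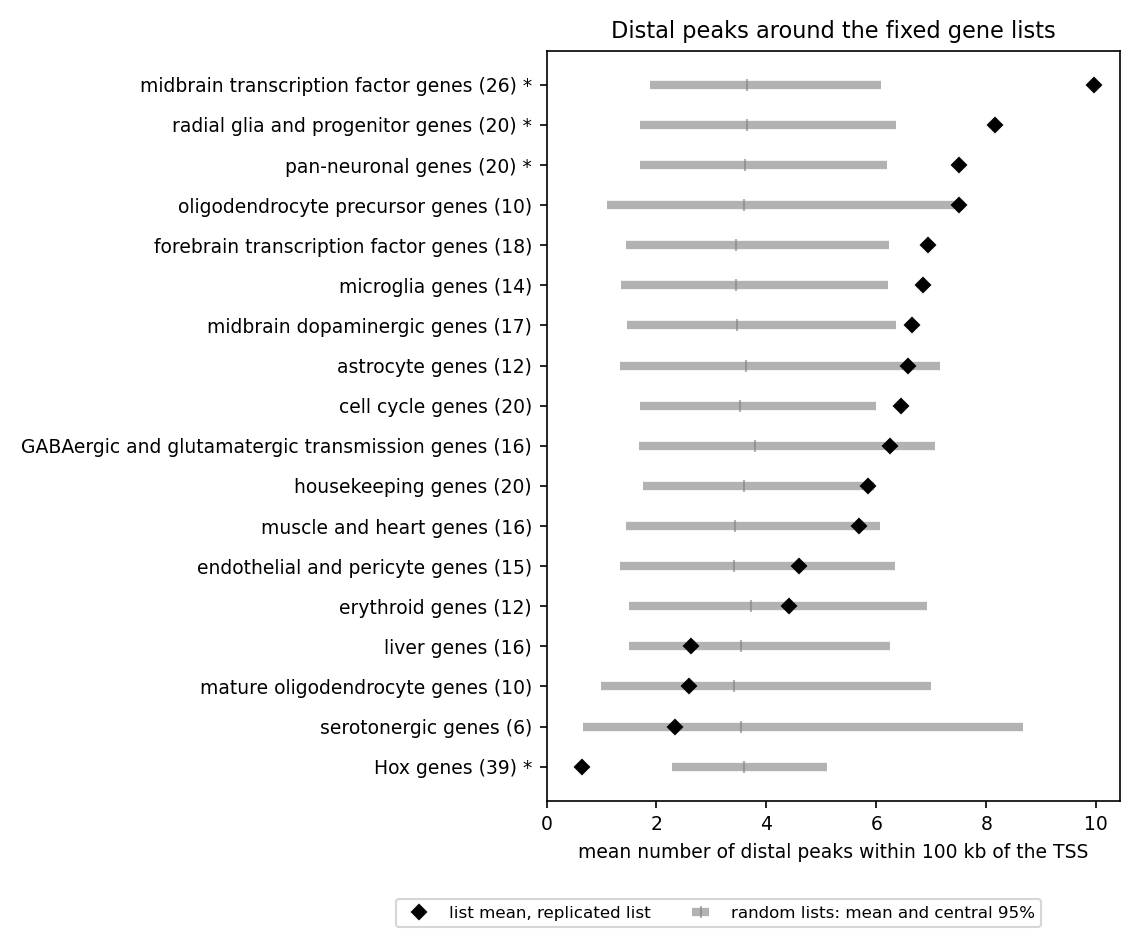
Mean number of replicated distal peaks within 100 kb of the TSS (horizontal axis) for each fixed gene list (diamonds) beside matched random lists (grey bars, central 95%, with a tick at their mean). Asterisks mark the lists past an adjusted p of 0.05, with midbrain transcription factor genes highest at 9.96 and Hox genes lowest at 0.641.

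The distal peaks formed 19322 domains when stitched within 10 kb, and the top 100 held 8.47% of the bases that distal peaks covered. Of these 100 domains, 70 were in the top 100 of each replicate. The largest lay in Msi2, which encodes an RNA-binding protein of neural progenitors, at chromosome 11, 88372533 to 88600159. It held 105 peaks covering 65528 bp, and covered 66084 bp in replicate 1 and 68621 bp in replicate 2, while the nearest protein-coding TSS was that of Ccdc182. The next was at Cstad on chromosome 2 (30591105 to 30726851), with 62959 bp. The domain nearest to Gins2 lay in Gse1 and covered 44771 bp, the domain nearest to Nnat reached into Blcap and Src with 44348 bp, and those nearest to Polg and Rhbg lay outside protein-coding genes with 41208 and 38746 bp. The domain nearest to Irf2bpl, also outside genes, covered 36929 bp. Those nearest to Ppif, Cep164 and Rapgef5 lay in Zmiz1, Dscaml1 and Ptprn2 with 36322, 35936 and 35309 bp. Members of the fixed lists nearest to a domain in the top 100, named here after that count was seen, were Sox2 and Notch1 of the radial glia list, Myt1l, Slc17a6 and Tfap2b.

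Among the 10 widest promoter peaks, 4 lay at members of the fixed lists. The widest covered the transcription factor gene Zfhx3 on chromosome 8 (108701024 to 108716981), with 15958 bp in the replicated list, of which 15690 bp were covered in replicate 1 and 15957 bp in replicate 2. It was followed by Tnrc18 at 13740 bp, Tcf7l2 at 12599 bp, Nrn1 at 11606 bp, Tfap2d at 11580 bp and Gad1, which makes GABA, at 10977 bp. Zmynd8 had 10934 bp, Msi1 10830 bp, Lhx5 10562 bp and Gnai2 9450 bp. Tfap2d and Lhx5 belong to the midbrain transcription factor list, Gad1 to the transmission list and Msi1 to the radial glia list.

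The consensus of regulatory factor X (RFX), GTTGCCATGG, was 5.84 ± 0.424 (SE over chromosomes) times as dense in distal peaks as in their flanks, and the highest of 100 permuted sequences reached 1.97. The MEF2 consensus had a ratio of 1.46 ± 0.0622 against a highest permuted ratio of 1.05. The POU octamer at 1.19 and the MEIS/TALE motif at 1.31 were each exceeded by 1 of 100 permutations. The homeodomain motif TAATTA had a ratio of 0.948, above all 13 of its permutations, whose median was 0.707. So few permutations cannot resolve a share of 5%, so this call is weaker than the other 4. Whether its ratio lay above or below 1 depended on the regions compared, with 1.503 against flanks matched on GC content and 0.666 in 200 bp around the summit. For MEF2 these ratios were 2.23 and 0.938, and for the POU octamer 1.57 and 0.883. For the HNF1 control, which has few occurrences, they were 1.27 and 0.284. The other 9 motifs were not called. Their ratios were 1.57 for CRE, 1.28 for the E-box, 1.19 for the NFI motif, 0.992 for SOX, 0.900 for AP-1, 0.882 for GATA, 0.844 for the HNF1 control, 0.828 for NR4A and 0.787 for the paired-like bicoid motif. In 200 bp around the summit 2 motifs were called in place of 5, the homeodomain motif and MEF2. The RFX ratio was 1.94 there and 8 of 100 permuted sequences reached it, while POU, reached by 5 of 100, lay at the threshold. MEIS/TALE was also not called with flanks matched on GC content, where its ratio was 1.18, and HNF1 was called without replicate 1, at a ratio of 1.23.

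**Figure D4:**
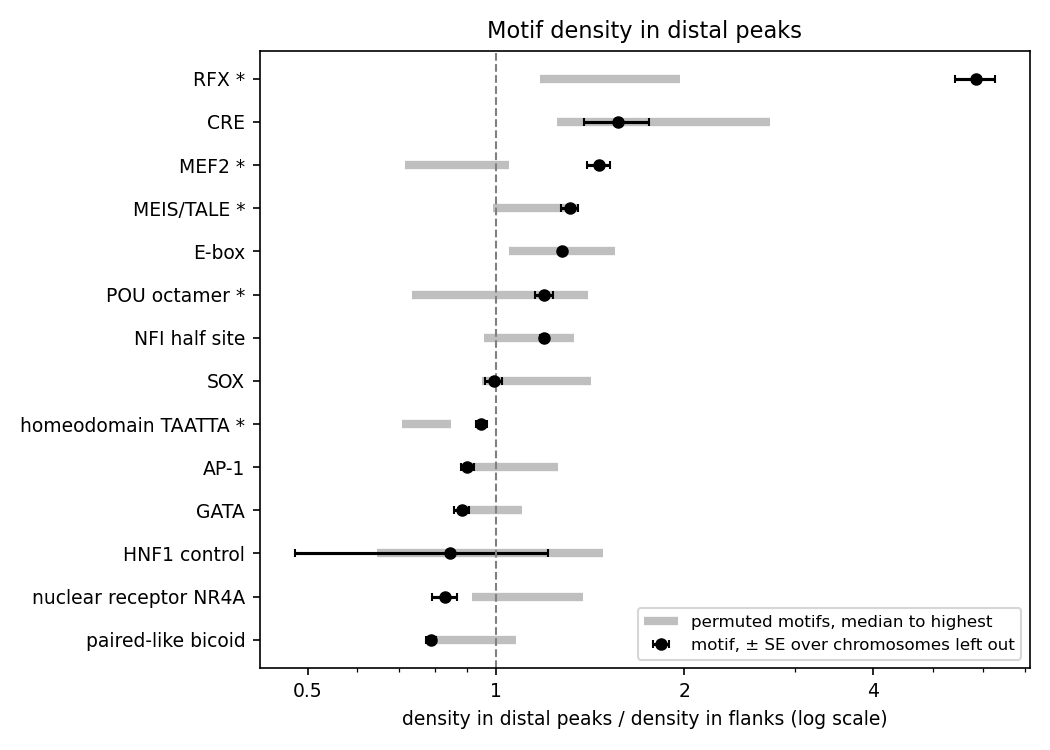
Density of each motif in 500 bp around distal summits divided by that in flanks (horizontal axis, log scale), with bars for the SE over chromosomes left out in turn. Grey bars run from the median to the highest ratio of permuted sequences, and asterisks mark the 5 motifs whose ratio fewer than 5% of them reached, with RFX highest at 5.84 and the homeodomain motif set against only 13.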

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

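Peaks outside the main chromosomes took no part in the comparisons. The replicated list held 9 of them, on 5 unplaced or unlocalized contigs. The highest signal among them was 48.5 and the widest was 1958 bp. A fixed rule flagged the count for lying above the 3 that a count of 0 would allow. Nothing in the design predicts a count of 0 there, so the flag only marks data left out. No explanation was tested.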

How the results depend on the processing

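Among the alternatives, those with the gene record's 5′ end, without genes with a second 5′ end within 2 kb, with genes of the same promoter CpG class, and with 1 member per 200 kb were chosen after seeing the data. For the promoter test, 172 of 198 combinations of list and alternative kept their direction and side of the threshold, 13 changed side and 13 changed direction. For the distal test, 137 of 162 kept both, 16 changed side and 9 changed direction. No list that changed direction was past the threshold before or after. The promoter count ranged from 8 lists (same CpG class) to 13 and the CpG odds ratio from 21.0 to 26.9. Of the top domains, 66 to 79 were in the top 100 of both replicates, and in the remaining replicate 80 were without replicate 1 and 76 without replicate 2. Of the 100 domains, 54 overlapped the top 100 ranked by signal times width. Unless stated, the cause of a change was not tested.

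The shared percentage of 61.9 was 39.7 with 50% reciprocal overlap, 52.6 with the summit in the other peak and 70.0 above the median signal, where fewer and stronger peaks are counted. The kept percentage of 78.1 was 98.1 above the median signal. In place of the authors' rule, 69.6% of pooled peaks overlapped a peak of both replicates by 1 bp and 53.6% by at least 50% of both peaks. The promoter percentage of 26.9 was 25.1 within 500 bp, 29.5 within 2 kb, 44.6 above the median signal, 22.7 in the pooled list, 31.3 with the TSSs of all genes, and 19.4 to 20.3 with a replicate left out.

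In the promoter test the mature oligodendrocyte list passed above the median signal (adjusted exact p = 0.0170), in the pooled list (0.0411), with replicate 1 peaks shared by replicate 2 (0.0125), without receptor families (0.0307) and with either replicate left out (0.0110 to 0.0388). The endothelial and pericyte list passed above the median signal (0.00657). The serotonergic list ranged from 0.0127 to 0.139 with a replicate left out, and failed without replicate 2. Without genes with a second 5′ end within 2 kb, the dopaminergic (0.0432) and oligodendrocyte precursor (0.0367) lists passed. Against genes of the same CpG class the midbrain transcription factor (1), microglia (0.283) and erythroid (0.150) calls were lost. The midbrain share was near that of its class, at 84.6% against 82.8%. Microglia genes, at 14.3% against 30.7%, and erythroid genes, at 8.33% against 31.5%, still lay below theirs.

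Directions changed, all short of the threshold, for endothelial and pericyte genes within 2 kb (adjusted exact p = 0.846), in the pooled list (0.800), within CpG class (0.800) and with either replicate left out (0.477 to 0.802), and within CpG class for cell cycle (0.271) and forebrain (0.800) genes. They did above the median signal for dopaminergic (0.861), oligodendrocyte precursor (0.615), astrocyte (0.340) and forebrain (1) genes, and for astrocyte genes with replicate 1 peaks shared by replicate 2 (1) and without receptor families (1). In the distal test they did for erythroid genes within 50 kb (0.809), for endothelial and pericyte (1), erythroid (0.886), liver (0.546) and muscle and heart (0.926) genes with the nearest TSS, and for mature oligodendrocyte (0.901), serotonergic (0.859) and liver (0.807) genes matched on a promoter peak. Mature oligodendrocyte genes ranged from 0.674 to 0.731 with a replicate left out, the direction changing without replicate 2.

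In the distal test 10 lists passed within 50 kb, the added ones being dopaminergic (adjusted permutation p = 0.0115), GABAergic and glutamatergic transmission (0.0268), oligodendrocyte precursor (0.0162), astrocyte (0.0392), forebrain transcription factor (0.00360) and housekeeping (0.0211). With peaks given to the nearest TSS 2 passed, radial glia (0.0504) and Hox (0.143) being lost. Random lists matched also on a promoter peak ended the pan-neuronal (0.115) and radial glia (0.0742) calls and gave a microglia call (0.00840). Above the median signal the pan-neuronal list failed (0.0936). With a replicate left out it ranged from 0.0270 to 0.0660 and microglia from 0.0288 to 0.0828, the change of call being without replicate 1 in both. With 1 member per 200 kb 2 lists passed, pan-neuronal (0.0927) and Hox (0.308) being lost, the latter with 4 members left. The microglia mean fell from 6.86 to 4.75 peaks there (adjusted permutation p = 0.452), because C1qa, C1qb and C1qc share their distal peaks.

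The motif count of 5 was 2 in 200 bp around the summit, where RFX (ratio 1.94), POU and MEIS/TALE were lost. POU and MEIS/TALE were reached there by 5 and 6 of 100 permutations, and their ratios over the permuted median were 1.47 and 1.28, against 1.62 and 1.33 in 500 bp. The POU ratio of peaks to flanks itself was 0.883 in 200 bp, against 1.19 in 500 bp, so its direction turned. The RFX consensus lay beside the summits, at 0.00861 per kb within 50 bp of them and 0.0512 per kb at 150 to 250 bp, so the narrower window holds few copies. MEIS/TALE was also lost with flanks matched on GC content, where NFI lay at the threshold (5 of 100), and HNF1, with few occurrences, passed without replicate 1. Unknown read depth limits what the absence of a weak peak can show.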

Other observations

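The patterns below were noticed in these data and tested on the same data. The tests of tissue composition and of base composition were chosen after the result was seen. The design holds 1 group. Of biological explanations only tissue composition was tested, and that test could not decide.

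Loci of brain microRNAs were among the largest distal domains. All 3 microRNA-9 genes lay in such a domain, Mir9-3 at rank 5 (chromosome 7, 79496214 to 79549523), Mir9-1 at rank 6 (chromosome 3, 88199747 to 88242613) and Mir9-2 at rank 14 (chromosome 13, 83713596 to 83753484). All 3 microRNA-124 genes did too, Mir124a-1 at rank 29, Mir124a-2 at rank 32 and Mir124a-3 at rank 49. Each of the 6 loci was also in the top 100 of both replicates. Both families are known from neural differentiation.

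Of the top 100 domains, 19 covered an annotated microRNA gene of any kind. Of 1000 random placements of the same domains 0 did so as often, the highest being 12. This argues only against placement at uniformly random positions, which were not matched on gene density. The 19 domains include those of the 5 loci first noticed, so the count is not independent of what prompted the test. Promoters of noncoding RNA genes, which count as distal here, may account for part of the pattern. Peaks within 1 kb of any annotated TSS were then left out. The rank taken was that of the highest remaining domain overlapping the original one, whether or not it covered the microRNA gene. By that measure 2 of the 5 loci first noticed (Mir9-1, at rank 62, and Mir9-3, at rank 85) stayed in the top 100, while Mir9-2 moved to 221, Mir124a-1 to 193 and Mir124a-2 to 444. Mir124a-3, which was not among the 5, moved to 302. This result lies between the bounds set for either answer, so promoters and distal elements of these loci cannot be told apart with this test. The annotated TSSs also include the 5′ ends of the microRNA genes themselves. Peaks over those genes were thus removed whether or not they were promoters, and the moves in rank do not measure the part of promoters.

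The RFX consensus stood out among the motifs. Base composition as the cause was argued against, since the ratio was 5.06 with flanks matched on GC content and 0 of 100 permuted sequences reached it. Repeats and repeated copies were also argued against, with a ratio of 5.63 outside repeat-masked sequence and of 5.60 when each region counted once. Occurrences lay in 1.45% of distal peak regions and 0.259% of flanks.

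Promoters of some gene lists ranked higher by signal in replicate 2 than in replicate 1. Among the 11817 genes with a promoter peak in both lists, the 12 forebrain transcription factor genes ranked 7.17 percentile points higher on average (8 of 12 higher) and the 22 midbrain transcription factor genes 6.13 (16 of 22 higher), but no list passed adjustment over the 11 lists tested (adjusted permutation p = 0.0704 for both, random lists matched on signal). The other lists lay inside the central 95% of random lists, with means from −4.09 for cell cycle genes to 5.22 for transmission genes, and no difference between regulators and other lists was tested. Matching on CpG content did not lower the forebrain shift. It was 7.47 points above such lists (central 95% −5.69 to 5.49, adjusted permutation p = 0.0539) and 7.22 without that matching. By the bound set beforehand CpG content did not account for the shift. Signal was matched there in coarser classes than without CpG content, so the values are not strictly alike. Yet the forebrain shift was the largest of the 11 lists and short of the threshold, so whether there was a shift to explain was not settled. Against lists matched on peak width the forebrain shift was 5.37 points (central 95% −5.75 to 5.70), inside the range set beforehand for width as the cause. Width removed only a part of the shift, so width was left open, a reading made after the value was seen. Matched on width, radial glia and progenitor genes, at −3.14 points, lay below random lists (central 95% −2.33 to 7.76, adjusted permutation p = 0.246), opposite to the pattern. More forebrain tissue in replicate 2 could not be separated from a shift of such genes in general, since the forebrain list exceeded the midbrain list by 1.03 points with an SD of 3.75, a spread too wide to exclude either.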
